A study of Mus musculus with 3 samples.

How the data were processed

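Single-cell RNA sequencing had been run on dissociated healthy adult mouse urethra in 3 droplet libraries, each loaded with about 17400 cells. The cold protease v2 library came from 1 mouse, was digested for 1 h in 10 mg/mL cold protease and was made with version 2 of the 10x Genomics 3' kit. The cold protease v3 library came from 2 pooled mice digested in the same way and used version 3 of the kit. The collagenase v3 library came from 1 mouse, was digested for 1 h in 1.5 mg/mL collagenase I and used version 3 of the kit. Per the labels, both protease libraries were re-analyses of earlier samples, no magnetic sorting was used, and the sequencer was either a NextSeq 500 or a NovaSeq 6000. Which sequencer served which library and the temperature of each digestion were not given in the sources used here.

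The deposited counts were raw UMI counts per gene and cell barcode, as filtered matrices of 32285 gene models. Cell Ranger 4.0.0 and the genome build mm10 are named in the submitters' processing notes, and the annotation release was not given in the sources used here. Whole-number values and a library total that differed between libraries were checked in each matrix. Models sharing a symbol were summed, which left 32245 symbols. Gene positions were not used here. The deposited totals were 36735032 UMIs over 15214 barcodes in protease v2, 165792612 over 14364 in protease v3 and 46442603 over 9021 in the collagenase library. Depth and animals differed between all libraries, so every ratio between libraries carries both. A ratio of collagenase over protease v3 also carries the enzyme but not the kit version. One between the protease libraries also carries the kit version, and one of collagenase over protease v2 carries enzyme and kit version.

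Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were retained. Doublet scores came from Scrublet in scanpy 1.11.5. Its automatic threshold called almost no barcodes, so the highest scoring barcodes were left out at a rate of 0.8% per 1000 barcodes, a step that departed from the plan. This removed 1344, 1112 and 351 barcodes from protease v2, protease v3 and collagenase, and left 10911, 11014 and 6549 cells. Each library was clustered on its own, on 209 marker genes of 28 cell types fixed in advance. Pearson residuals (theta 100, clipped at 10) were reduced to 30 principal components, joined in a graph of 15 neighbours and clustered with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). A cluster of at least 10 cells was named for a cell type when at least 2 of its markers stood among the 30 leading genes and a marker score reached 0.4. A second way in needed 1 such marker, a score of 0.7 and 8 detected markers. Either way, at least 3 markers of the type had to be detected. The 10 leading genes could not hold more markers of another class, or a close mix of both. Leading genes needed 100 CPM (UMIs of a gene scaled to a common total per summed cluster), with 20 CPM added to both sides of the ratio. The first form of the rule required a score of 0.5 with no second way in. It was loosened once after its names had been seen, and the first form is among the alternatives. Umbrella cell clusters were counted as luminal, also after the data had been seen. Clusters with markers of more than one lineage were meant to be left out. They stayed unnamed and count among the cells that shares are taken of. A cluster with a median depth under 0.333 of its library's median also stayed unnamed if no marker of its type stood among its 10 leading genes. Class names are by markers and are written as "like" that cell type.

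Differential expression used summed raw UMI counts per library and class, with classes of at least 20 cells. Luminal-like against basal-like cells and fibroblast-like against smooth muscle-like cells were compared with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) in R 4.3.3, with library as a block. The pairing comes from the design, since both classes of a library come from the same animals and the same tube. This left 2 residual degrees of freedom among libraries, from 3 libraries. Each class present in at least 2 libraries was also compared with the unweighted mean of the other classes in one fit with library as a term. P values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. The 209 markers that defined the classes were left out of counts and named genes. Under DESeq2 1.42.0 the adjustment included the markers, which were removed afterwards. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated correlation. With an estimated correlation camera uses the 2 residual degrees of freedom, so few lists can pass, whereas at a preset one it does not. Adjustment was over 26 lists.

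Each combination of enzyme and kit had 1 library, so no test was made between digestions. In classes with at least 50 cells in every library, a gene counted as higher with collagenase when its CPM was at least 2 times that of both protease libraries. The higher side needed at least 25 UMIs and 50 CPM. A gene counted as lower in the mirror case, with these minimums then needed in both protease libraries. The same count with each protease library set against the other libraries gave the scale of differences between any of them. For lists, the median log2 ratio of collagenase v3 over protease v3 was taken over members with at least 10 UMIs, with a pseudocount of 0.5 UMIs. Its percentile came from 10000 random lists of the same size drawn from 20 expression bins, and lists outside the range from 2.5 to 97.5 were counted. Shares and folds carry exact 95% intervals (binomial for shares, and the binomial form of the ratio of Poisson counts for folds). A count of 0 was bounded at 3 counts, over the class sum. Intervals and bounds cover counting error only.

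The 26 lists held 390 genes, of which 389 were found by symbol. Cyr61 was not found because the files name it Ccn1. The lists were immediate early genes, heat shock, cytokines and NF-kB targets, antimicrobial defence, MHC class I, MHC class II, interferon response, basement membrane and its adhesion, tight junction, desmosome, ion and water transport, retinoid and xenobiotic metabolism, androgen and steroid response, Wnt, Notch, Hedgehog, BMP and TGF-beta, EGF family, FGF with HGF and IGF, extracellular matrix proteases and inhibitors, elastic fibre and matrix, contractile and calcium handling, fibroblast zone genes, proliferation, glycolysis and hypoxia, and mitochondrial transcripts. Named genes followed a rule. For each pair of classes it took the 12 genes with the largest fold in each direction among those past the threshold, alike in every library and with a mean of at least 50 CPM in the higher class. For each class against the others it took the 4 genes with the largest fold, by the same requirements. Between digestions it took 10 genes in each direction in the 2 classes with the most cells in their smallest library, and 3 in the other classes. Between digestions a gene whose CPM in the class lay under 0.2 of its CPM in another class of the library was not named, since free RNA could give it. Markers, mitochondrial and ribosomal protein genes, haemoglobins and provisional gene models were not named. Some genes taken by the rule are not reported here. Genes outside the rule are named as members of a list, or as the leading genes of a cluster.

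Alternatives were a loose filter (200 genes, 30% mitochondrial UMIs), a strict filter (1000 genes, 10%), doublets retained, clustering on 2000 highly variable genes, resolution 2, DESeq2, DESeq2 size factors within edgeR, no filter on low counts, no library block and each library left out. Between digestions they were a 3-fold rule, a minimum of 10 UMIs and 20 CPM, TMM scaling, each cell thinned to 1000 UMIs and ratios over protease v2. A subtraction of 10% free RNA and a count without genes that free RNA could give were also run. The tests, lists, named gene rule and these alternatives were fixed before the data were examined.

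On simulated sums with a dispersion of 0.05, chosen by hand, and 200 changed genes, the paired test recovered 40.4% of 2-fold and 100% of 4-fold changes between luminal-like and basal-like sums, with 2.48% false calls. Between fibroblast-like and smooth muscle-like sums it recovered 23.9% and 100%, with 5.66% false calls. On simulated counts the size rule between digestions recovered 100% of 2.5-fold changes in luminal-like and 50% in macrophage-like cells. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.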

Results

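Transcripts of single cells from healthy adult mouse urethra were counted as UMIs in 3 libraries. The cold protease v2 library (1 mouse) held 15214 barcodes and 36735032 UMIs, with a median of 1812 UMIs and 847 genes per barcode. The cold protease v3 library (2 pooled mice) held 14364 barcodes and 165792612 UMIs, with a median of 8362 UMIs and 2654 genes. The collagenase v3 library (1 mouse) held 9021 barcodes and 46442603 UMIs, with a median of 3936 UMIs and 1558 genes. The median mitochondrial share per barcode was 6.05%, 8.97% and 6.32% in that order. After filtering, 10911, 11014 and 6549 cells remained, with medians of 2080, 9590 and 4957 UMIs. The transcript Xist, which silences an X chromosome in female cells, stood at 1.52, 0.32 and 0.215 CPM. The Y-linked RNA helicase Ddx3y stood at 67.9, 50.9 and 156.8 CPM. Protease v3 and collagenase shared version 3 of the kit but differed in enzyme, animals and depth. The protease libraries shared the enzyme but differed in kit version, animals and depth. Each combination of enzyme and kit had 1 library, so no test was made between digestions.

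Epithelial cells made up most of the named cells after cold protease, and stromal cells most after collagenase. This comparison asks which cell types each digestion released. Luminal-like epithelial cells (Krt8, Krt18, Psca) were 25.1% of cells in protease v2 (exact 95% interval 24.3 to 25.9), 44.5% in protease v3 (43.5 to 45.4) and 10.99% with collagenase (10.25 to 11.78). Basal-like epithelial cells (Krt5, Trp63) were 20.03% (19.29 to 20.8), 14.02% (13.38 to 14.68) and 3.53% (3.094 to 4.003). Fibroblast-like cells (Col1a1, Dcn) were 7.70% (7.21 to 8.22), 4.37% (3.99 to 4.77) and 33.5% (32.4 to 34.7). Cells like blood endothelium (Pecam1, Cdh5) were 4.01% (3.65 to 4.40), 2.98% (2.67 to 3.31) and 20.98% (20 to 21.99). The collagenase share was 4.35 times the higher protease share for fibroblast-like cells and 5.23 times for endothelium-like cells. Intervals did not overlap between any pair of libraries for these 4 classes, but they cover counting error only and not the spread between animals or preparations.

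Smaller classes were spread unevenly over the libraries. Smooth muscle-like cells (Acta2, Myh11) were 1.93%, 0.4% and 2.61% of cells, and macrophage- and monocyte-like cells (Csf1r, C1qa) 1.07%, 1.34% and 2.89%, in protease v2, protease v3 and collagenase. Cells like T and NK lymphocytes were 0.917% in protease v2 and 1.77% with collagenase, and pericyte-like cells 0.385% and 1.80%. Satellite-like cells, the stem cells of skeletal muscle, were 0.431% and 0.327% in protease v2 and v3, and neuroendocrine-like cells (Chga, Syp) 0.467% and 0.227%. Cells like the epithelium of seminal vesicle or ductus deferens (Svs5, Pate4) were 6.28%, 6.45% and 0.29%. The protease v3 share includes a cluster of 227 cells led by Crisp1, Cyp4a12a and Spink8. Protease v2 clusters of 550 and 472 cells that also had Cyp4a12a and Spink8 among their leading genes stayed unnamed. For a class with 0 named cells, counting error alone allowed up to 0.0275%, 0.0272% and 0.0458% of cells in protease v2, protease v3 and collagenase, a limit that leaves out cells unnamed or named otherwise. In protease v3 an unnamed cluster of 66 cells had the T and NK genes Ccl5, Gzma and Nkg7 and the B cell gene Cd79a among its leading genes. Protease clusters of 376 and 213 cells led by Sprr1a and Krt5 were named basal-like, while a collagenase cluster of this kind was named squamous-like. A cell filter of 200 genes and 30% mitochondrial UMIs lowered the luminal-like share of protease v3 to 32.5%, and the first form of the naming rule lowered it to 31.2%. Clusters were named by their markers, and 31.7%, 17.4% and 13.5% of cells stayed unnamed. In protease v3 these included a cluster of 1475 cells at a median of 1154 UMIs, 0.12 of the library median. Shares are taken of such shallow cells too.

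**Figure D1:**
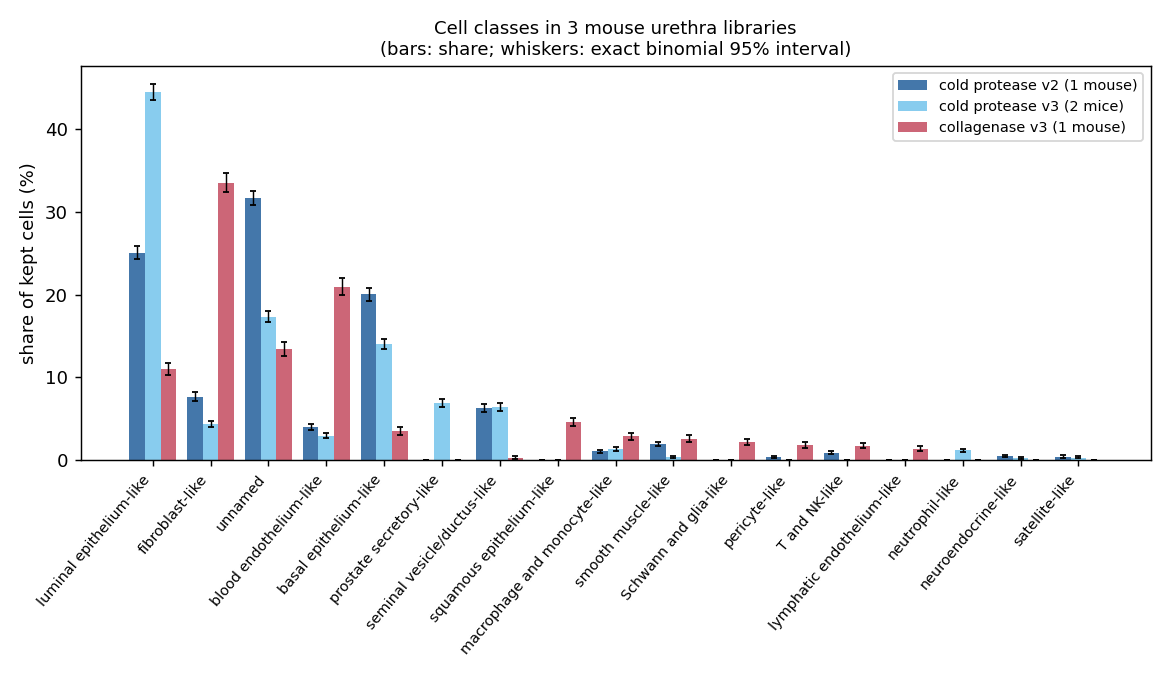
Share of kept cells (percent) in each marker-named class, one bar per library, with exact 95% binomial intervals that cover counting error only. Fibroblast-like cells reached 33.5% with collagenase against 7.70% and 4.37% in the protease libraries.

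Luminal-like cells of the urethra were set apart from basal-like cells by Olfm4 and Areg, and basal-like cells by Grp and Lgals7. The comparison asks what separates the surface layers of the epithelium from the layer on the basement membrane. Luminal-like cells were higher in Olfm4, a secreted glycoprotein (log2 fold change 4.49 ± 0.32 SE, edgeR adjusted p = 2.09e-05, higher in 3 of 3 libraries), which averaged 94.1 ± 95.2 CPM against 2.33 ± 1.16 (SD, n = 3). They were higher in Areg, a ligand of the EGF receptor (4.36 ± 0.21, edgeR adjusted p = 8.24e-06, 3 of 3 libraries), although its luminal level was 2.07 and 9.09 CPM in protease v2 and v3 and 2255 CPM with collagenase. Basal-like cells were higher in Grp, the gastrin-releasing peptide, at 483.1 against 18.2 CPM (-4.77 ± 0.29, edgeR adjusted p = 1.16e-05, 3 of 3 libraries). Galectin 7, from Lgals7, averaged 1092 CPM in basal-like and 65.5 CPM in luminal-like cells (-4.41 ± 0.24, edgeR adjusted p = 9.38e-06, 3 of 3 libraries).

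Of 12390 genes tested with edgeR, 1868 were higher and 1695 lower in luminal-like than in basal-like cells. Among those with the largest folds, each in the same direction in 3 of 3 libraries, were the small GTPase Arl14 (4.36), tissue plasminogen activator Plat (3.96), the chemokine Ccl6 (3.74), the serine protease Prss27 (3.72) and Clca1, a secreted protein of mucus (3.71). Then came Spns2, an exporter of sphingosine 1-phosphate (3.46), the lipoxygenase Alox15 (3.43), the mucosal chemokine Cxcl17 (3.07) and Bex1 (3.07). On the basal side stood Dlk2, a membrane protein with EGF-like repeats (-4.51), Edaradd, the adaptor of the ectodysplasin receptor (-3.53), the cadherin Cdh13 (-3.53) and the transcription factor Snai2 (-3.43). Further basal genes were the adhesion molecule Sdk1 (-3.36), the phospholipid carrier Pltp (-3.25), the alarmin Il33 (-3.24), the Notch ligand Jag2 (-3.24), podoplanin from Pdpn (-3.21) and the tensin Tns4 (-3.21). Adjusted p of the named genes was at most 1.74e-04, for Cxcl17. Luminal Arl14 stood at 2.80 and 3.50 CPM in protease v2 and v3 and at 271 CPM with collagenase. Luminal Plat stood at 6.08 and 10.26 CPM and at 194.4 CPM. Both reached a mean of 50 CPM through the collagenase library. The count was 1576 without the protease v3 library, and 182 without the library block, of which all 182 were among the 3563 called with it. Sums of luminal-like cells joined clusters led by Ppp1r1b, Psca, Ly6d, Spink5, Lypd2, Upk3a, Fxyd2, Areg or Clu. The Fxyd2 cluster (305 cells) was from protease v3, and a protease v2 cluster of 517 cells led by Igkc and Fxyd2 stayed unnamed.

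**Figure D2:**
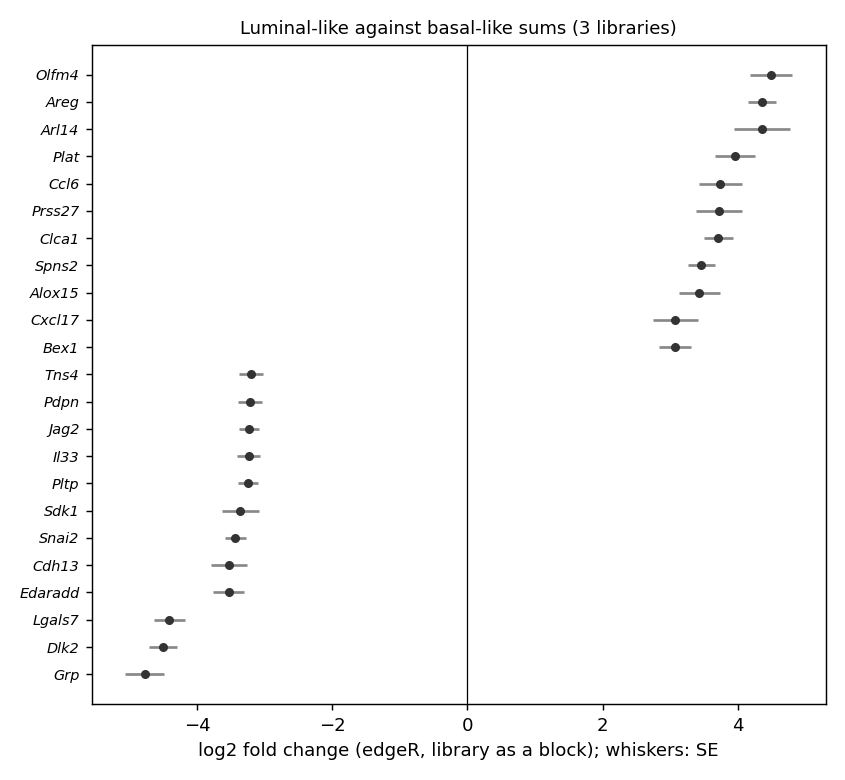
Log2 fold change of luminal-like over basal-like cells from edgeR with library as a block, for 23 genes named by rule, with whiskers of 1 SE (3 libraries). Olfm4 stood at 4.49 and Grp at -4.77.

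Of 26 gene lists, 16 passed camera between the layers at its preset correlation and 0 with an estimated one. The estimated form rests on 2 residual degrees of freedom, so its higher p values do not show that inter-gene correlation undid the calls. The contractile list had an estimated correlation of -0.059, below the preset 0.01, yet its camera p went from 6.29e-05 to 0.0528. Of 13 tested tight junction genes, 11 were higher in luminal-like cells and 1 lower (11 and 1 adjusted over the list alone), with Cldn23 at 2.73 and Cldn1 at -2.02. The list passed camera (median 1.04, adjusted p = 8.16e-05, and adjusted p = 0.482 with an estimated correlation). Of 13 ion and water transport genes, 9 were higher and 2 lower (9 and 2 adjusted over the list alone), among them the bicarbonate cotransporter Slc4a4 (3.37) and the sodium channel Scnn1a (2.05), while the water channels Aqp3 (-1.49) and Aqp4 (-3.33) were lower (camera adjusted p = 0.00181, and adjusted p = 0.408 with an estimated correlation). Antigen presentation by MHC class I had 7 of 12 genes higher and 0 lower (9 and 0 adjusted over the list alone), with Psmb8 at 1.37 and H2-K1 at 0.88 (camera adjusted p = 6.78e-04, and adjusted p = 0.482 with an estimated correlation). The interferon response had 8 of 17 higher and 2 lower (8 and 2 adjusted over the list alone), with Ifi44 at 2.34 and Ifitm3 at -1.50 (camera adjusted p = 0.0308, and adjusted p = 0.545 with an estimated correlation). The EGF family had 5 of 9 higher and 2 lower (5 and 2 adjusted over the list alone), with betacellulin from Btc at 2.95 and Nrg1 at -3.04 (camera adjusted p = 0.0316, and adjusted p = 0.482 with an estimated correlation). Mitochondrial transcripts passed camera upward with 1 of 11 members past the threshold, mt-Nd3 at 0.49 (0 adjusted over the list alone; camera adjusted p = 0.0373, and adjusted p = 0.596 with an estimated correlation).

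On the basal side, 14 of 18 basement membrane and adhesion genes were lower in luminal-like cells and 2 higher (14 and 2 adjusted over the list alone). Col7a1, the collagen of anchoring fibrils, stood at -3.00, Col4a2 at -2.72 and Lama3 at -1.88, while Lamb2 stood at 0.71 (camera adjusted p = 8.16e-05, and adjusted p = 0.482 with an estimated correlation). Proliferation genes were lower in 10 of 14 (12 lower and 1 higher adjusted over the list alone), with Ube2c at -2.72, Top2a at -2.21 and Mki67 at -2.04 (camera adjusted p = 8.16e-05, and adjusted p = 0.482 with an estimated correlation). Contractile and calcium handling genes were lower in 8 of 10 (8 adjusted over the list alone), with Smtn at -2.42 and Tpm2 at -2.41 (camera adjusted p = 4.09e-04, and adjusted p = 0.408 with an estimated correlation). Fibroblast zone genes (1 higher, 5 lower of 11, 1 and 8 adjusted over the list alone) passed at adjusted p = 0.00259, and adjusted p = 0.408 with an estimated correlation, with Apoe at -2.94. Elastic fibre and matrix genes (1 and 5 of 11, 1 and 6 adjusted over the list alone) and BMP and TGF-beta genes (1 and 7 of 11, 1 and 7 adjusted over the list alone) each passed camera at adjusted p = 0.00398, and adjusted p = 0.408 with an estimated correlation. Sparc stood at -2.49, Bmp4 at -2.10 and Bmp2 at 1.71.

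Wnt genes were lower in 4 of 10 (5 adjusted over the list alone), with Wnt10a at -3.97 and the secreted inhibitor Sfrp1 at -3.38 (camera adjusted p = 0.0316, and adjusted p = 0.482 with an estimated correlation). FGF, HGF and IGF genes had 1 higher and 5 lower of 10 (1 and 5 adjusted over the list alone), with Igfbp2 at -2.82 (camera adjusted p = 0.0296, and adjusted p = 0.539 with an estimated correlation). Desmosome genes had 1 higher and 5 lower of 10 (2 and 6 adjusted over the list alone), with Pkp1 at -1.64 and Pkp2 at 1.99 (camera adjusted p = 0.0373, and adjusted p = 0.565 with an estimated correlation). Immediate early genes, which are induced within minutes of a stimulus, had 1 higher and 7 lower of 19 (3 and 8 adjusted over the list alone), with Egr1 at -1.08 (camera adjusted p = 0.0373, and adjusted p = 0.561 with an estimated correlation). Without the collagenase library the calls of immediate early genes (adjusted p = 0.846, with the sign reversed), mitochondrial transcripts (0.401) and the interferon response (0.0671) were lost. Without protease v3 those of the interferon response (0.804), Wnt (0.0668) and desmosome genes (0.0668) were lost. The lists that did not pass camera were heat shock (adjusted p = 0.172), cytokines and NF-kB targets (0.968), antimicrobial defence (0.311), MHC class II (0.378), retinoid and xenobiotic metabolism (0.112), androgen and steroid response (0.447), Notch (0.508), Hedgehog (0.112), extracellular matrix proteases (0.17) and glycolysis and hypoxia (0.509). The cytokine list had a median of -0.09 although camera placed it upward. Within these lists, 8 of 17 retinoid and xenobiotic genes were higher and 2 lower (8 and 3 adjusted over the list alone), with Cbr2 at 1.66, and 4 of 8 antimicrobial genes were higher and 2 lower (4 and 3 adjusted over the list alone), with lactoferrin from Ltf at 2.86 and the antibody transporter Pigr at 2.72.

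Fibroblast-like cells were set apart from smooth muscle-like cells by Sult1e1 and Clec3b, and smooth muscle-like cells by Pln and Tnnt2. The comparison asks how the stromal cell types of the urethra differ. Sult1e1, which sulfates oestrogens, gave 5360 UMIs in fibroblast-like and 0 in smooth muscle-like cells, at least 173.9-fold higher over the summed libraries (edgeR adjusted p = 1.81e-04, 3 of 3 libraries). Clec3b, the plasminogen-binding tetranectin, averaged 373.2 ± 117.3 CPM against 3.02 ± 5.23 (SD, n = 3; log2 fold change 6.48 ± 0.46 SE, edgeR adjusted p = 7.43e-05, 3 of 3 libraries). Smooth muscle-like cells were higher in Pln, phospholamban, the regulator of the calcium pump, at 447.8 ± 342.6 against 0.452 ± 0.434 CPM (-8.71 ± 0.61, edgeR adjusted p = 7.23e-05, 3 of 3 libraries). Tnnt2, a troponin T, averaged 224.7 against 0.973 CPM (-8.41 ± 0.39, edgeR adjusted p = 2.68e-05, 3 of 3 libraries).

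With edgeR, 800 genes were higher and 695 lower in fibroblast-like than in smooth muscle-like cells, of 8938 tested. On the fibroblast side stood Hsd11b1, which activates glucocorticoids (at least 44.1-fold higher, 0 UMIs in smooth muscle-like cells), the B cell chemokine Cxcl13 (7.10), the Wnt deacylase Notum (6.45), complement component C7 (6.02), the lipopolysaccharide binding protein Lbp (5.27), the ferritin receptor Scara5 (4.97), Serpinf1 (4.91), the gelatinase Mmp2 (4.84), the noradrenaline transporter Slc6a2 (4.84) and the serine protease Htra3 (4.70). On the muscle side stood Fam81a (at least 349.3-fold lower, 0 UMIs in fibroblast-like cells), Map3k7cl (-8.00), Susd5 (-7.46), Slc38a11 (-7.07), Rgs4, a brake on G protein signalling (-7.04), Nrip2 (-6.98), the calmodulin-binding Pcp4 (-6.93) and Pcp4l1 (-6.82), myomesin from Myom1 (-6.70) and junctophilin from Jph2 (-6.61). All of these held in 3 of 3 libraries, with adjusted p of at most 5.24e-04, for Mmp2. Fitted folds of Cxcl13, Notum, Map3k7cl and Susd5 rest on 1 to 3 UMIs in the lower class. The count was 668 without the protease v2 library, 900 without protease v3 and 314 without the library block, and the protease v3 library gave 44 smooth muscle-like cells. It was 159 under the strict cell filter, where fewer libraries had enough cells, and 2392 without a filter on low counts.

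**Figure D3:**
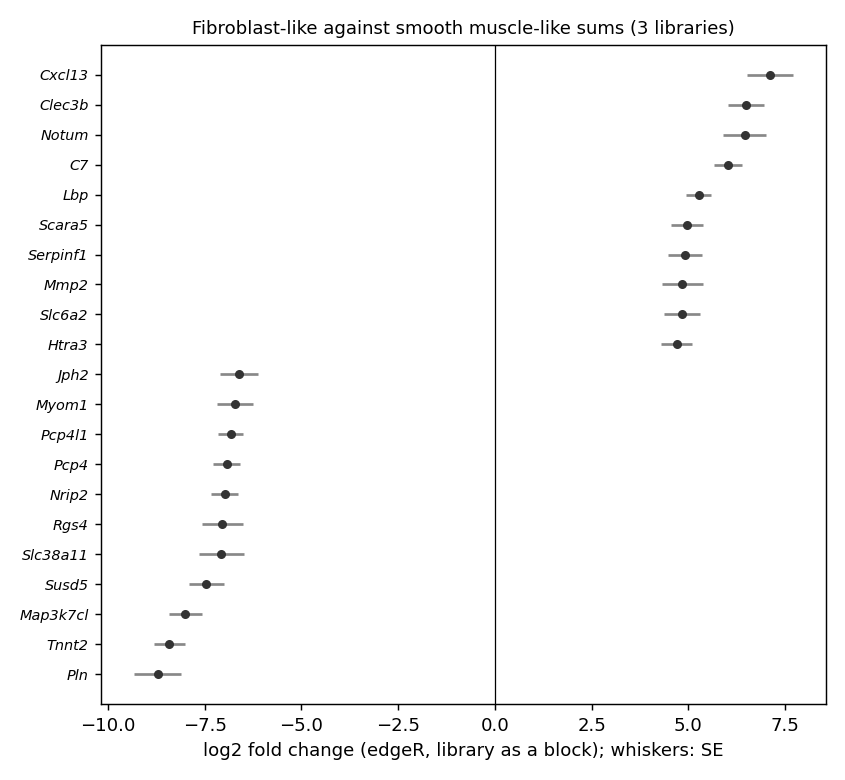
Log2 fold change of fibroblast-like over smooth muscle-like cells from edgeR with library as a block, for 21 genes named by rule, with whiskers of 1 SE (3 libraries); Sult1e1, Hsd11b1 and Fam81a, with 0 UMIs in one class, are not drawn. Clec3b stood at 6.48 and Pln at -8.71.

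Of 26 gene lists, 11 passed camera between these stromal classes at the preset correlation and 0 with an estimated one. Here too the estimated form had 2 residual degrees of freedom, so the 0 does not tell whether inter-gene correlation matters. Contractile and calcium handling genes were lower in fibroblast-like cells in 14 of 14 tested (14 adjusted over the list alone), with the coactivator Myocd at -6.59, Mylk at -5.94 and the ryanodine receptor Ryr2 at -5.20 (median -4.58, camera adjusted p = 2.89e-16, and adjusted p = 0.437 with an estimated correlation). Elastic fibre and matrix genes were higher in 13 of 18 and lower in 0 (14 and 1 adjusted over the list alone), with elastin from Eln at 3.54 and Fbln2 at 3.50 (camera adjusted p = 3.07e-10, and adjusted p = 0.437 with an estimated correlation). Fibroblast zone genes were higher in 9 of 11 (10 higher and 1 lower adjusted over the list alone), with complement C3 at 4.67, the Wnt amplifier Lgr5 at 3.01 and Osr1 at 1.86 (median 3.003, also with Sult1e1 at its bound, camera adjusted p = 3.93e-07, and adjusted p = 0.437 with an estimated correlation). Wnt genes were higher in 6 of 12 and lower in 0 (7 and 0 adjusted over the list alone), with the inhibitor Wif1 at 3.70 and Wnt2 at 2.52 (camera adjusted p = 0.00221, and adjusted p = 0.458 with an estimated correlation). Extracellular matrix proteases were higher in 7 of 13 and lower in 1 (7 and 2 adjusted over the list alone), with Timp2 at 1.60 and Adamts5 at -1.80 (camera adjusted p = 0.00221, and adjusted p = 0.445 with an estimated correlation). Mitochondrial transcripts were lower in 11 of 11 (11 adjusted over the list alone), with mt-Nd5 at -0.94 and mt-Atp6 at -0.52 (camera adjusted p = 3.07e-10, and adjusted p = 0.437 with an estimated correlation).

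Glycolysis and hypoxia genes had 2 higher and 5 lower of 17 (2 and 10 adjusted over the list alone), with Hif1a at -1.30 and Gapdh at -0.78 (camera adjusted p = 0.00221, and adjusted p = 0.437 with an estimated correlation). Androgen and steroid response genes had 3 higher of 9 (3 adjusted over the list alone), Ndrg1 at 1.56 among them (camera adjusted p = 0.0239, and adjusted p = 0.437 with an estimated correlation). Retinoid and xenobiotic genes had 6 higher of 18 (7 adjusted over the list alone), with the retinoic acid enzyme Aldh1a3 at 3.75 (camera adjusted p = 0.0449, and adjusted p = 0.458 with an estimated correlation). Cytokines and NF-kB targets had 2 higher of 9 (2 adjusted over the list alone), with Il33 at 2.63 (camera adjusted p = 0.0289, and adjusted p = 0.437 with an estimated correlation), and the sign reversed without protease v2 (adjusted p = 0.995) or protease v3 (adjusted p = 0.964). The interferon response had 4 higher of 15 (5 adjusted over the list alone; camera adjusted p = 0.0492, and adjusted p = 0.721 with an estimated correlation). Its call was lost without protease v3 (adjusted p = 0.126), and that of androgen and steroid genes without collagenase (adjusted p = 0.0789). Camera gave adjusted p = 0.0524 for heat shock and for Notch, 0.0587 for MHC class I and for desmosome, and 0.0904 for FGF, HGF and IGF. It gave 0.154 for Hedgehog, 0.338 for basement membrane, 0.365 for tight junction, 0.49 for ion and water transport, 0.614 for antimicrobial defence and for the EGF family, 0.747 for immediate early genes and for MHC class II, 0.781 for proliferation and 0.801 for BMP and TGF-beta. Antimicrobial defence (median 0.05) and MHC class II (median 0.09) had medians above 0 although camera placed them downward. In lists short of the threshold, 3 of 7 Notch genes were lower (3 adjusted over the list alone), with Nrarp at -3.59 and Jag1 at -1.39, and the growth factor genes Igf1 and Fgf10 stood at 4.56 and 2.08.

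Each class was also set against the mean of the others, which asks what marks each cell type beyond the markers used to name it. The genes with the largest folds (log2) included the granule protease Gzmb in T and NK-like cells (12.95, 1066 CPM), the membrane protein Ms4a7 in macrophage-like cells (12.76, 758.3 CPM) and the synaptic Snap25 in neuroendocrine-like cells (12.04). The proton channel Otop1 (13.03), Resp18 (12.44) and the vesicle gene Rab3c (12.10) were also higher in neuroendocrine-like cells, in 2 of 2 libraries, and the matrix proteases Mmp12 (11.59) and Mmp13 (11.58) and the complement receptor C5ar1 (11.55) in macrophage-like cells, in 3 of 3. Fibroblast-like cells were higher in Cilp (9.18), Notum (8.41), Wif1 (7.74) and C7 (7.68), endothelium-like cells in Enpp6 (9.51), Hmcn1 (9.09), Cytl1 (8.998) and Meox1 (8.85), and smooth muscle-like cells in Pln (10.18), Map3k7cl (9.72), Susd5 (9.24) and Carmn (9.12), each in 3 of 3 libraries. Pericyte-like cells were higher in vitronectin from Vtn (9.31), Casq2 (9.13), the endothelin receptor Ednrb (8.76) and the chemokine Ccl11 (8.19), and satellite-like cells in the natriuretic peptide gene Nppc (11.67), C1qtnf3 (11.25), Fitm1 (10.81) and Nctc1 (10.80), each in 2 of 2. Ccl11 differed between the pericyte-like sums, at 2031 ± 2625 CPM (SD, n = 2), as did Vtn, at 674.2 ± 809.7 CPM. The 42 pericyte-like cells of protease v2 also held Prol1 at 29793 CPM, against 18426 CPM over all UMIs of that library. Sh2d2a (12.31), Klra9 (12.19) and Krt83 (12.05) completed the T and NK-like genes in 2 of 2. In 3 of 3 libraries, luminal-like cells were higher in Prss27 (5.73), Olfm4 (5.42), Liph (4.76) and Nectin4 (4.69), and basal-like cells in Dlk2 (6.01), the glutamate transporter Slc17a8 (5.59), Grp (5.14) and Lgals7 (4.76). Seminal vesicle-like cells were higher in Pate8 (8.83), Orm3 (7.90), Slc6a14 (6.99) and Spinkl (6.67), in 2 of 2. These are fitted folds, which depend on the prior count where other classes were near 0 and can exceed the ratio of mean levels. Nppc averaged 519.5 against 3.37 CPM in the other classes, C1qtnf3 149.8 against 1.06 and Krt83 52.3 against 0.155 CPM.

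Of 12878 genes, edgeR called 3559 in fibroblast-like, 3461 in luminal-like, 3072 in seminal vesicle-like, 3011 in macrophage-like, 2657 in endothelium-like, 2429 in smooth muscle-like and 2340 in basal-like cells. It called 1383 in T and NK-like, 1076 in neuroendocrine-like, 721 in pericyte-like and 473 in satellite-like cells. Adjusted p of the named genes was at most 6.65e-05, for Fitm1. Without the protease v3 library the counts were 2127 for fibroblast-like, 1971 for macrophage-like, 1653 for endothelium-like, 1401 for smooth muscle-like and 1439 for basal-like cells. DESeq2 called 5473 genes for luminal-like cells.

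Immediate early genes stood higher in the collagenase library than in the same classes of either protease library. The comparison asks how the digestion is reflected in gene expression within a class. In fibroblast-like cells Fos, an AP-1 transcription factor, stood at 6.92 and 1.98 CPM in protease v2 and v3 and at 2231 CPM with collagenase, 1129-fold over protease v3 (95% interval 518.6 to 3076). The chemokine Cxcl10 stood at 3.46 and 1.65 CPM and at 788.2 CPM, 478.6-fold over protease v3 (205.0 to 1474). In luminal-like cells Areg stood at 2.07 and 9.09 CPM and at 2255 CPM, 248.0-fold over protease v3 (229.4 to 268.4). Gstp1, a glutathione transferase, was lower with collagenase in luminal-like cells, at 55.97 and 107.1 CPM and at 18.7 CPM.

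The size rule counted 450 genes higher and 84 lower with collagenase in luminal-like cells, 378 and 63 in basal-like, 425 and 131 in fibroblast-like, 390 and 159 in endothelium-like and 479 and 53 in macrophage-like cells. With protease v2 as the odd library the counts were 114 and 122, 146 and 144, 228 and 201, 281 and 295, and 140 and 300 in the same order of classes. With protease v3 as the odd library they were 17 and 30, 27 and 23, 82 and 27, 63 and 34, and 173 and 17. With collagenase as the odd library 95 genes were higher in all 5 classes and 4 lower, against 44 and 22 with protease v2 and 5 and 5 with protease v3. The 95 genes included Atf3, Fos, Fosb, Egr1, Jun, Junb, Hspa1a, Dnajb1, Cebpb, Nfkbia, Plaur, Hbegf and Cdkn1a. The median log2 ratio of all genes over protease v3 was -0.16 in luminal-like and basal-like, -0.40 in fibroblast-like and endothelium-like and -0.42 in macrophage-like cells. TMM scaling brought it to -0.10, -0.04, -0.03, -0.03 and -0.00, and gave 611 higher and 46 lower genes in fibroblast-like and 629 and 67 in endothelium-like cells.

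**Figure D4:**
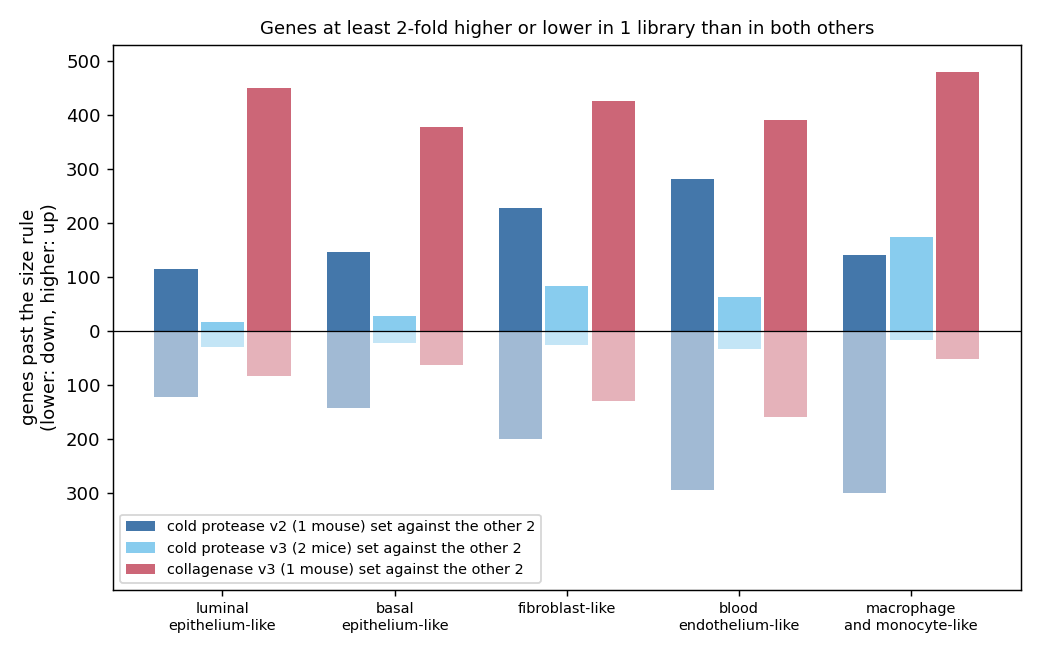
Number of genes at least 2-fold higher (up) or lower (down, paler) in 1 library than in both others, in 5 cell classes, with each library in turn as the odd one. The collagenase library gave 378 to 479 higher genes per class, and the protease libraries 17 to 281.

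In luminal-like cells the named genes furthest above protease v3 were Fosl1 (128.1 CPM with collagenase against 1 UMI, 9269.5-fold, 95% interval 1660.4 to 366439.3), Fosb (1612.2-fold, 1099 to 2470), Ccn1 (279.3-fold), Areg, its relative Ereg (245.2-fold), Atf3 (234.0-fold), the nuclear receptor Nr4a3 (201.7-fold), the urokinase receptor Plaur (177.2-fold), Tnfrsf12a (94.2-fold) and thrombospondin from Thbs1 (94.2-fold). Over protease v2 the folds were smaller for Ccn1 (114.6), Nr4a3 (50.4), Plaur (78.6), Tnfrsf12a (79.5) and Thbs1 (42.5) and larger for Areg (1090), Ereg (571.0) and Atf3 (341.7). Of these Areg, Ereg, Atf3 and Plaur stood at 0.243 to 13.8 CPM in both protease libraries. The named genes lower with collagenase, as a multiple of the protease v3 level, were Klhdc7a (0.173), Gstp1 (0.175), Pgp (0.232), the noncoding Snhg20 (0.244), Rassf9 (0.249), Mylip (0.252), the protease inhibitor Spink5 (0.252), Mrpl34 (0.261), the glutathione peroxidase Gpx2 (0.261) and Smim5 (0.267). Spink5 was higher with collagenase when the loose filter (log2 ratio 0.79) or the first naming rule (0.82) was used, and led a luminal-like cluster of 1152 cells in protease v3. Luminal-like cells with collagenase fell into clusters of 417 cells led by Areg and Psca, 256 led by Clu and Spink8 and 47 led by Ly6d and Crisp1. Clusters with Clu and Spink8 among their leading genes stayed unnamed in protease v2 (1088, 550 and 472 cells) and protease v3 (186 cells). One with Fxyd2 and Ly6d stayed unnamed in protease v2 (517 cells). The luminal-like sums thus held different kinds of cells in each library, and the luminal counts, folds and list medians carry this difference.

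In fibroblast-like cells Fosb had 3 UMIs in protease v2, 0 in protease v3 and 1887 CPM with collagenase, at least 1910.0-fold over protease v3. Fos, Nr4a3 (504.9-fold, 95% interval 90.5 to 19952, 1 UMI in protease v3), Atf3 (503.1-fold), Cxcl10, the hyaluronan synthase Has1 (404.7-fold), Thbs1 (359.6-fold, 99.5 to 2971, 2 UMIs in protease v3), Angptl7 (233.4-fold, 64.5 to 1928, 2 UMIs) and the collagen Col8a1 (169.3-fold, 30.3 to 6696, 1 UMI) followed. Folds over protease v2 were smaller for Fos (322.3), Cxcl10 (227.8), Thbs1 (68.5), Angptl7 (35.5) and Col8a1 (21.5). Lower with collagenase were Snhg20 (0.158 of protease v3), the protease Adamts15 (0.192), the transcription factor Hand2 (0.193), Mid1ip1 (0.204), Rpp25l (0.214), Thy1 (0.219), the transcription factor Osr1 (0.221), Hand2os1 (0.251), BC003965 (0.265) and Izumo4 (0.269). Osr1 stood at 949.1 and 858.6 CPM in protease v2 and v3 and at 189.9 CPM with collagenase. Fibroblast-like cells formed 1 cluster in each protease library and 4 with collagenase, of 740 (Eln, Mfap4, Pi16), 723 (Ifi205, C3, Cxcl13), 690 (Angpt1, Fst, Wif1) and 42 cells (Kera, Tnmd).

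In basal-like cells Fosb (2892-fold, 95% interval 1236 to 8920), Fos (1202-fold, and 475.7-fold over protease v2) and Fosl1 (at least 1029-fold) were furthest above protease v3, and Gstp1 (0.208), Snhg20 (0.209) and Polr2l (0.276) furthest below. In endothelium-like cells they were Cxcl10 (416.7-fold, 202.2 to 1037), Atf3 (190.3-fold) and the selectin Sele, which slows leukocytes on the vessel wall (189.7-fold, 1761 CPM with collagenase), and Gstp1 (0.119), Cytl1 (0.12) and Snhg20 (0.148). Collagenase endothelium-like clusters of 652 and 572 cells were themselves led by Selp and Sele. In macrophage-like cells the chemokines Ccl7 (2332-fold, 418 to 92140, 1 UMI in protease v3), Cxcl2 (1868-fold, 638.7 to 9060, 3 UMIs in protease v3) and Ccl2 (222.2-fold) were furthest above. Ccl7 was 13.9-fold and Ccl2 86.7-fold above protease v2. Below stood the protease inhibitor Slpi, Ppfia4 (0.246) and Zmynd15 (0.248). Slpi stood at 799.4 and 2111 CPM in protease v2 and v3 and at 0 UMIs with collagenase, at least 235.3-fold and 621.5-fold lower. In protease v3 no cluster held more Slpi by CPM than the macrophage-like one.

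All 23 measured members of the immediate early list were above the protease v3 level in each of the 5 classes, and 20, 21, 22, 20 and 17 passed the size rule in luminal-like, basal-like, fibroblast-like, endothelium-like and macrophage-like cells. The median log2 ratio was 4.90, 5.35, 5.67 (5.66 with members at 0 set to their bound), 3.89 and 4.30 (3.98 at the bound), above every one of the 10000 random lists. Heat shock genes had medians of 1.42, 1.42, 1.61, 1.35 and 1.14, with 9, 9, 12, 10 and 10 of 16 members past the rule, and the chaperone Hspa1a went from 15.5 and 31.5 to 858.7 CPM in luminal-like cells. Cytokines and NF-kB targets had medians of 5.03, 1.98, 3.73 (2.997 at the bound), 3.39 and 3.84 (3.37 at the bound). Of these, 4 of 21, 3 of 13, 9 of 18, 8 of 16 and 11 of 19 members passed the rule, with Nfkbia, the inhibitor of NF-kB, among them in endothelium-like cells (177.0 and 378.4 to 2730 CPM) and Tnf in macrophage-like cells (5.84 and 4.88 to 363.5 CPM). Extracellular matrix proteases and inhibitors had medians of 1.95, 1.58, 1.24, 0.76 and 2.07, with Timp1 at 13.84 and 25.03 and at 200.7 CPM in fibroblast-like cells.

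Elastic fibre and matrix genes had medians of 2.34, 1.94, 1.59, 0.35 and -0.40, the last of which was 0.02 under TMM scaling. In fibroblast-like cells 9 of 19 passed the rule, with Sparc at 873.0 and 1699 and at 5697 CPM and Postn 10.0-fold over protease v3, while in luminal-like cells Sparc stood at 9.004 and 4.82 and at 31.8 CPM. Fibroblast-like cells were 33.5% of the collagenase library, and the luminal Sparc level lay under 0.2 of theirs. The rule that left possible free RNA out of named genes was not applied to list medians or to counts of lists. Free RNA may therefore contribute to them, in this list and in the others. Tight junction genes were above protease v3 in luminal-like and basal-like cells (1.60 and 0.82), with Cldn7 at 141.3 and 354.3 and at 1442 CPM in luminal-like cells. They were below it in fibroblast-like, endothelium-like and macrophage-like cells (-0.43, -0.33 and -1.42), although the endothelial median was 0.03 under TMM scaling and the macrophage one 0.72 over protease v2 (-0.05 at the bound). Desmosome medians were 1.12, 0.79, -1.75, -0.76 and -2.19. Retinoid and xenobiotic genes had medians of -0.21, -0.71, -0.83, -1.40 and -2.49, and over protease v2 the luminal, basal and fibroblast medians were 0.94, 0.41 and 0.13. Cyp2f2, at 1182 and 2162 CPM in luminal-like cells of protease v2 and v3, stood at 192.1 and 217.7 CPM in fibroblast-like cells there and at 33.1 CPM with collagenase. Antimicrobial defence had a median of -3.74 in macrophage-like cells (-2.21 at the bound).

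Of 26 lists, 14 lay above and 0 below the range of random lists in luminal-like cells, 14 and 1 in basal-like, 10 and 4 in fibroblast-like and 10 and 2 in endothelium-like cells, and 5 and 7 of 25 did so in macrophage-like cells. Svs5, a seminal vesicle secretory protein, made up 33337 and 32440 CPM of all UMIs in protease v2 and v3 and 1651 CPM with collagenase, and in fibroblast-like cells it stood at 4326, 3352 and 191.1 CPM. The secretory Pip stood at 1027, 86.3 and 454.2 CPM in fibroblast-like cells. In fibroblast-like cells the growth factor Igf1 was 8.17-fold, and Sult1e1 13.9-fold, over protease v3, and in endothelium-like cells the interferon regulator Irf1 was 20.3-fold. Igf1 and Sult1e1 were also among the leading genes of the collagenase fibroblast-like cluster of 723 cells and not of those in the protease libraries.

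**Figure D5:**
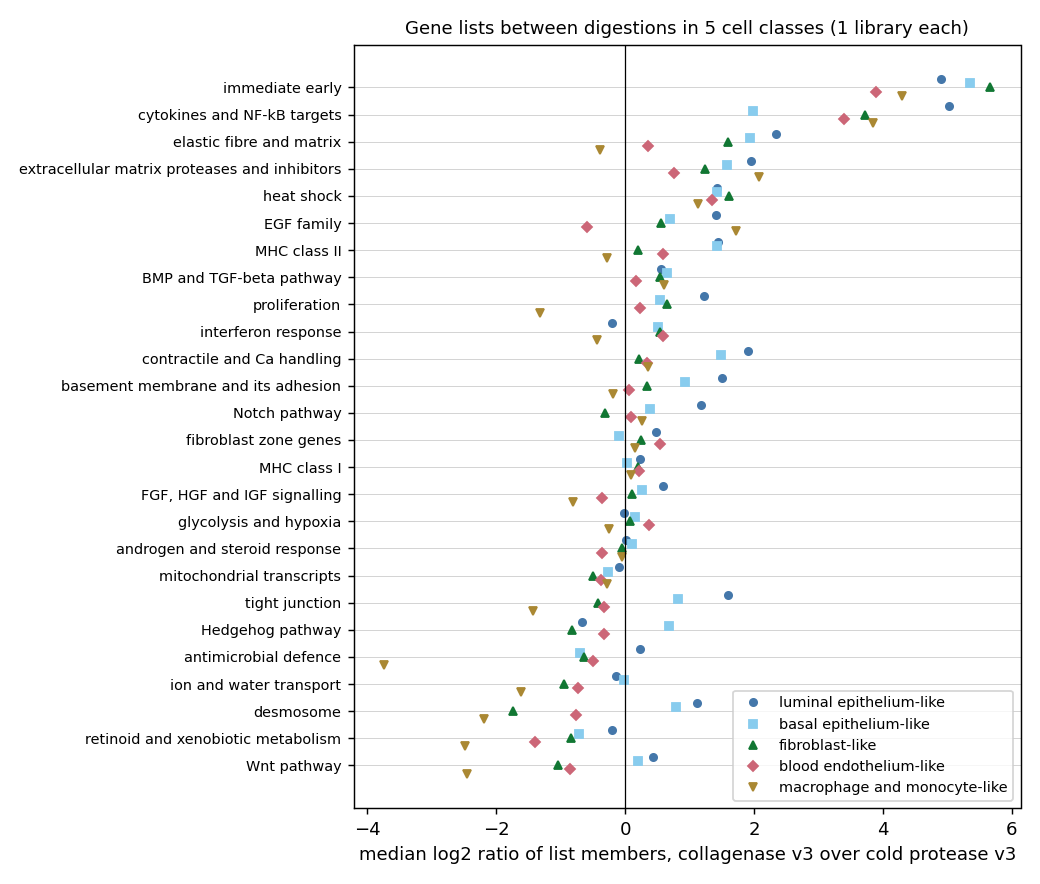
Median log2 ratio of collagenase v3 over cold protease v3 for the members of 26 gene lists, 1 point per cell class. Immediate early genes lay between 3.89 and 5.67 in the 5 classes.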

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

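The tests of depth and of digestion for the immediate early genes, each test for the stromal cells and the test of kit version for Svs2 were chosen after the result was seen, and the others before.

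Immediate early genes stood higher in the collagenase library than in both protease libraries, in each of the 5 classes compared. The tables argue against depth as the whole cause, since with each cell thinned to 1000 UMIs the lowest median log2 ratio over either protease library was 3.61. They argue against free RNA from 1 source, which would hold the members at 1 ratio in every class, since a member's share of the list varied over classes by a median of 2.89-fold. They argue against another mix of clusters inside the classes, since the lowest median over the collagenase clusters was 3.89. Digestion may be the source, but it cannot be told apart from the animal or its handling with 1 collagenase library, and the 0 list members higher with a protease library as the odd one follow from the pattern itself.

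Fibroblast-like and endothelium-like cells took larger shares of the collagenase library than of both protease libraries. The tables argue against the cell filter, doublet removal or cluster naming as the whole cause, because the lowest ratio of the collagenase share to the higher protease share was 3.27 under the alternatives, in fibroblast-like cells under the loose filter. A loss of shallow cells from the protease libraries was not decided. Summed over all deposited barcodes, fibroblast markers were 15.2-fold and endothelial markers 8.15-fold above the higher protease library (571.0 and 403.6 to 8668 CPM, and 116.2 and 63.1 to 947 CPM). Barcodes passing the filter held 34535110 of 36735032 UMIs in protease v2 and 158660056 of 165792612 in protease v3, so these sums could hardly have come out otherwise. The matrices were filtered before deposit, so cells lost earlier were not seen. Collagenase may have released more stroma, a biological reading that was not tested. It cannot be told apart from the part of the tract that was taken, since prostate-like and seminal vesicle-like cells made up 0.29% of the collagenase library against 6.28% and 13.3% in protease v2 and v3. These shares count named clusters only. The protease v3 share includes 227 cells with Spink8 and Cyp4a12a among their leading genes, while such clusters of 1088, 550 and 472 cells in protease v2 stayed unnamed. A collagenase cluster of 435 cells with Msmb and Pbsn among its leading genes also stayed unnamed. It was shallow, with a median of 1436 UMIs, 0.29 of the library median, and 0 detected markers of prostate epithelium. Prol1 stood at 22569 CPM in it, while Pbsn was 6.61 CPM of all UMIs of the library. Free RNA could give such genes, which was not tested, so its cells cannot be taken as prostate-like.

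Svs2 was low beside Svs5 in both v3 libraries, with 0.00527 and 0.00883 Svs2 UMIs per Svs5 UMI in protease v3 and collagenase and 0.452 in protease v2. By the test set in advance, a different mix of seminal vesicle-like clusters stayed a candidate, because the highest v3 cluster (0.0831) lay above the lowest protease v2 cluster (0.0272). That v3 cluster held 29252 Svs5 UMIs and was led by Crisp1 and Cyp4a12a. The protease v3 cluster with 4845862 Svs5 UMIs stood at 0.00433 and the collagenase cluster at 0.00774, below every protease v2 cluster. These values argue against another mix of the protease v2 clusters alone as the source. Kit version may also be the source: the v3 libraries differed by 1.67-fold from each other, and protease v2 lay 85.6-fold above protease v3. It cannot be told apart from the animal, since the only v2 library came from 1 mouse. No biological explanation was tested.

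Several groups of cells appeared in data that no comparison used. Unnamed clusters held 3460 cells in protease v2, 1912 in protease v3 and 882 with collagenase. Classes named in 1 library alone, with at least 20 cells, were 141 cells like Schwann cells and glia, 92 like lymphatic endothelium and 301 like squamous epithelium with collagenase. In protease v3 they were 131 neutrophil-like cells and 757 cells like prostate secretory epithelium. A name given in 1 library does not show that the cells were absent from the others: protease clusters of 376 and 213 cells led by Sprr1a were named basal-like, and the neutrophil-like cluster also had the monocyte genes Lyz2 and Ccr2 among its leading genes, as did an unnamed cluster of 104 cells in protease v2. A cluster found in 1 library can be that library rather than a cell type. Between luminal-like and basal-like cells, and between fibroblast-like and smooth muscle-like cells, 0 genes were at least 2-fold apart in one direction with collagenase and in the other in both protease libraries, a comparison that was not tested.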

How the results depend on the processing

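In each case below the cause was not tested unless its construction shows it. Among the main counts and shares, 235 alternative values stayed near the main value and 79 moved. The stricter cluster naming was chosen after seeing the data.

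The loose filter gave basal-like shares of 17.9% and 13.2% in protease v2 and v3, luminal-like shares of 22.9% and 32.5%, endothelium-like cells at 4.99% and fibroblast-like cells at 9.71% of protease v2, fibroblast-like cells at 31.7% of the collagenase library, 141 lower genes in macrophage-like cells and Spink5 at 0.79 in luminal-like cells (main -1.99). The strict filter gave basal-like 10.1% and 16.4%, luminal-like 30.3% and 48.5% and fibroblast-like 1.38% and 5.76% in protease v2 and v3, and endothelium-like 1.36% in protease v2. It left 48 lower genes in endothelium-like and 35 in fibroblast-like cells and 159 genes between fibroblast-like and smooth muscle-like cells, where fewer libraries had enough cells. It turned Col4a2 to 0.17 (main -0.81) and Gpx3 to -0.33 (main 2.22) in that comparison, and macrophage-like cells were too few for a value between digestions. Retained doublets gave basal-like 16.5% and luminal-like 41.2% in protease v3, fibroblast-like 8.37% and luminal-like 21.9% in protease v2, 177 lower genes in macrophage-like cells and Rsad2 at -0.22 between luminal-like and basal-like cells (main 1.28). Clustering on highly variable genes gave basal-like 3.60% and 12.8% in protease v2 and v3, luminal-like 40.9% in protease v3 and 2362 genes between luminal-like and basal-like cells, with Apod at -0.49 (main 1.09), and Lcn2 at 0.70 between fibroblast-like and smooth muscle-like cells (main -1.76). Resolution 2 gave basal-like 16.2% in protease v3 and 4.21% with collagenase, luminal-like 40.7% in protease v3, and endothelium-like 17.5% and fibroblast-like 27.6% with collagenase. Stricter cluster naming gave luminal-like 31.2% in protease v3 and Spink5 at 0.82.

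Between digestions, the 3-fold rule by its construction gave fewer genes, 214 higher and 11 lower in basal-like, 238 and 45 in endothelium-like, 260 and 17 in luminal-like and 286 and 19 in macrophage-like cells, and 36 lower in fibroblast-like cells. The minimum of 10 UMIs and 20 CPM by construction admitted more genes. It gave 567 higher and 231 lower in basal-like, 510 and 511 in endothelium-like, 600 and 451 in fibroblast-like, 624 and 234 in luminal-like and 631 and 219 in macrophage-like cells. TMM scaling gave 629 and 67 in endothelium-like and 727 and 24 in macrophage-like cells and 46 lower in fibroblast-like cells. Thinning to 1000 UMIs gave 148 lower in basal-like, 75 lower in endothelium-like and 272 higher and 18 lower in macrophage-like cells. Over protease v2 the medians of opposite sign, among lists outside the random range in the main analysis, were retinoid and xenobiotic metabolism in basal-like (0.41) and fibroblast-like cells (0.13), fibroblast zone genes (-0.78) and mitochondrial transcripts (0.49) in endothelium-like cells, mitochondrial transcripts in fibroblast-like (0.12), Notch in luminal-like (-0.45) and tight junction in macrophage-like cells (0.72). Lists inside that range also changed sign, among them retinoid and xenobiotic metabolism (0.94) and the interferon response (0.92) in luminal-like cells.

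In the class comparisons, which pair classes by a library block, a fit with no replicate block gave 182 genes between luminal-like and basal-like and 314 between fibroblast-like and smooth muscle-like cells. Against the other classes it gave 850 for T and NK-like, 846 for basal-like, 1562 for endothelium-like, 1993 for fibroblast-like, 1596 for luminal-like, 1976 for macrophage-like, 681 for neuroendocrine-like, 1532 for seminal vesicle-like and 1457 for smooth muscle-like cells. DESeq2 gave 5473 for luminal-like cells against the others. Without a filter on low counts 2392 genes passed between fibroblast-like and smooth muscle-like cells. With an estimated correlation 0 lists passed camera in either comparison, against 16 and 11 at the preset one. The estimated form has 2 residual degrees of freedom, so the loss cannot be put down to correlation. With each library left out in turn, counts ranged from 1576 to 3934 between luminal-like and basal-like and from 668 to 1857 between fibroblast-like and smooth muscle-like cells. Against the other classes they ranged from 1439 to 2416 for basal-like, 1653 to 2648 for endothelium-like, 2127 to 3634 for fibroblast-like, 1971 to 3142 for macrophage-like and 1401 to 2006 for smooth muscle-like cells. Camera reversed its sign for cytokines between fibroblast-like and smooth muscle-like cells without protease v2 and without protease v3 (adjusted p from 0.0489 to 0.995 over the libraries left out) and for immediate early genes between luminal-like and basal-like cells without the collagenase library (9.84e-05 to 0.846). Lists short of the threshold also changed sign. Between fibroblast-like and smooth muscle-like cells these were the EGF family with any 1 library left out, immediate early genes without protease v3, and heat shock, antimicrobial, tight junction, ion transport and BMP and TGF-beta genes without collagenase. Between luminal-like and basal-like cells they were cytokines without collagenase.

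Of the smaller class shares 170 alternative values stayed and 64 moved. Of named genes and list members in class comparisons 3849 kept direction and side of the threshold, 780 lost the call in the same direction and 5 reversed. Of lists in class comparisons 157 stayed, 34 lost and 12 gained the call and 3 reversed, where a change of sign counted only for a list past the threshold in the main or the alternative test. Between digestions 536 values of named genes stayed, 36 moved and 2 reversed, and 221 list medians stayed, 29 moved and 7 reversed. Depth limits the smallest class sums, such as the 44 smooth muscle-like cells of protease v3 and the 117 macrophage-like cells of protease v2, and the 163 of 438 endothelium-like cells of protease v2 that thinning left out.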

Other observations

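Some unnamed clusters were shallow. In protease v3 one of 1475 cells (13.4% of kept cells), with Malat1 and Neat1 among its leading genes, had 0.12 of the library's median UMIs. One of 105 cells there had 0.139, and one of 435 cells with collagenase had 0.29. Other unnamed clusters held gland-like and immune transcripts that no comparison described. In protease v2, a cluster of 461 cells was led by Apod and the secretory Prol1 and one of 214 cells by Mup20 and Smr2, with Prol1 at 121607 and 80398 CPM. Clusters of 80 cells in protease v3 and 50 cells with collagenase held Prol1 at 193672 and 57712 CPM. Protease v2 clusters of 1088, 550 and 472 cells were led by genes among Crisp1, Akr1b7, Cyp4a12a and Spink8. A collagenase cluster of 131 cells joined Igha (6368 CPM) and Jchain (3507 CPM), genes of secreted antibody, with the dendritic gene Cd209a and the cytokine gene Il1b. A collagenase cluster of 25 cells was led by the skeletal muscle genes Mylpf and Tnnt3, and one of 149 cells by genes that included Wif1, Asb5 and Gal.

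Pbsn, a secretory protein of the prostate, stood at 7.00, 2709 and 6.61 CPM of all UMIs in protease v2, protease v3 and collagenase, and in fibroblast-like cells of protease v3 at 938.7 CPM. Pip stood at 3327, 433.3 and 2992 CPM of all UMIs.

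The splits of the paired comparisons were chosen as a test after their result was seen, and the draws for single classes before. When class labels were dealt again within each library, 1 of 21 draws, the real one, called as many genes as observed for luminal-like (3461, highest other 638), basal-like (2340, 283), fibroblast-like (3559, 785), smooth muscle-like (2429, 563), endothelium-like (2657, 473) and macrophage-like cells (3011, 654). The classes had been made by clustering the same cells on expression, so their sums were bound to differ more than dealt labels, and these draws do not exclude chance. For luminal-like against basal-like and fibroblast-like against smooth muscle-like cells the 10 splits of 6 sums are too few for a share under 0.05. The real splits called 3563 and 1495 genes, and the highest other split 0 in each, also among the 4 splits that part all pairs.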
